A study of Homo sapiens with 21 samples.

How the data were processed

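Gene expression was measured on 21 arrays of HEY cells, a human ovarian cancer cell line, with 3 arrays in each of 7 groups. The groups were untransfected cells at 0 h, cells given a synthetic control miRNA at 24, 48 and 144 h, and cells given mir-429 at the same times. Per the labels' protocols, cells were transfected with a lipid reagent, total RNA was extracted on columns, and it was amplified and biotin labelled with a kit that primes from the 3' end. The labels call the comparison arm synthetic miRNA, and it was taken as the negative control that the series' design names. Replicates are labelled as biological, but nothing says how the cultures were separated, so p-values measure the spread between these samples. The labels give no scan date or batch.

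The deposited values are log2 expression values per probe set made by RMA, per the submitters' processing notes; the version and software are not given in the sources used here. They ran from 0.75 to 14.97, with array medians between 3.95 and 4.29, and no further scaling was applied in the main setting. The table held 54675 probe sets. GEO's platform annotation gave 1 gene symbol to 41097 of them, several to 1801 and none to 11777. Symbols were updated through Entrez identifiers with a RefSeq table of assembly GRCh38.p14, which matched 99.9% of them, and probe sets with several symbols were not named. A gene was represented by the probe set with the highest mean over all arrays, which gave 19775 genes. Genes were tested where that probe set lay above the array median in at least 3 arrays, which left 12879 genes and set aside 6896. Arrays give no read depth, and their number limits the precision. No coordinates are printed, because the array table names no genome build.

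Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) on a model with a mean for each of the 7 groups, with 14 residual degrees of freedom and a prior of 3.93. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 9 comparisons were mir-429 against control at each time and averaged over times, the differences of that effect between 24 and 48 h and between 48 and 144 h, and control against untransfected cells at each time. Values are log2 changes ± SE from this fit with n = 3 per group unless stated. The SE of a gene pools its spread over all 7 groups, so it is the same in each comparison of single groups. The spread was not equal. The SD of the difference between arrays of the same group was 0.17 to 0.25 in untransfected cells and 0.39 to 0.47 in control cells at 48 h. In control cells at 24 h it was 0.24 to 0.45. The SE may thus be too small at 48 h, and perhaps in comparisons with control cells at 24 h. It may be too large where the arrays of a group lay closer. This also affects how counts compare between times. Where the mean of a dim group lay below its array medians, the change is a bound (at least, or at most for a fall), with the values of that group raised to the array median. The 15 gene lists held miR-200 family targets described before, epithelial, mesenchymal, actin and cell motility, DNA replication and S phase, mitosis, interferon response, inflammatory NF-kB, cholesterol synthesis, hypoxia and glycolysis, p53 target, unfolded protein and amino acid stress, and YAP and TGF-beta response genes, and leukocyte and endothelial markers. They were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 15 lists of a comparison. A list called or not called is so by this test unless another is named. Camera with an estimated correlation and fry were alternatives. Fry asks whether the members move one way on balance and does not compare them with other genes. The comparisons, lists, tests, alternatives and the rule for named genes were fixed before the data were examined.

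Named genes were the 10 largest rises and 10 largest falls past the threshold in each mir-429 comparison at a single time. The values of the groups compared were not to overlap, within each time for the averaged comparison, and genes without an official symbol were passed over. The averaged comparison took 5 in each direction, each difference between times 4, and each control comparison 6. Up to 4 members per list with the smallest p were added in mir-429 comparisons at single times and up to 2 in control comparisons. ZEB1, ZEB2, CDH1, EPCAM, VIM, FN1 and CDH2 were always named.

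The test script was checked on simulated data for the 24 h comparison over 12879 genes. It recovered 38.8% of 67 genes changed by 0.5, 88.1% of 67 changed by 1 and 100% of 66 changed by 2 on the log2 scale. Of 161 calls 10 were false, and a comparison simulated without any change gave 0 calls. The noise was drawn independently between genes, with the same spread in all groups and no difference in RNA quality. The simulation thus checks the script and does not give the share of false calls in the real arrays. Array quality was described by the 3' minus 5' difference of the GAPDH and ACTB control probe sets, which grows as RNA fragments or amplification stops short. The alternatives fixed beforehand covered the filter, the summary of probe sets, scaling, eBayes options, array weights, the arrays in the fit, a replicate block, the threshold and leaving out each array. Leaving out the 48 h arrays and a covariate of the 3' to 5' difference, the mean of GAPDH and ACTB on each array, were added after seeing the data, as were checks of the lists under each scaling and without each array. A test fixed beforehand of mir-429 seed matches in 3' UTRs was not run, because transcript sequences were not used here. Mature mir-429 was not analysed here, so transfection itself was not checked. Figures were drawn with matplotlib 3.10.9.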

Results

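The series followed mRNA levels in HEY ovarian cancer cells after transfection with mir-429, a member of the miR-200 family of microRNAs, or with a control miRNA. Arrays were made before transfection and at 24, 48 and 144 h, with 3 arrays in each of 7 groups. The 3' minus 5' signal of the GAPDH control transcript was 7.01 ± 0.53 (SD, n = 3) in control and 7.88 ± 0.26 in mir-429 arrays at 48 h, and the mir-429 and control means at 24 and 144 h lay between 0.74 and 1.58. The 48 h arrays of both arms thus had much less 5' signal. Averaged over GAPDH and ACTB, the difference at 24 h was 2.87 in mir-429 and 4.21 in control arrays (exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). At 48 h it was 8.55 and 7.83 (exact permutation p = 0.2), and at 144 h it was 3.35 and 3.90 (exact permutation p = 0.2). Of the markers of other cell types, 4 leukocyte and 10 endothelial genes passed the filter, and camera called neither list in any of the 9 comparisons. Fry, which does not compare a list with other genes, put endothelial markers lower with mir-429 at 24 h and in control at 24 and 48 h (adjusted p = 0.0123, 0.000169 and 1.27e-05). It put leukocyte markers higher in control at 24 h and lower at 48 h (adjusted p = 0.00871 and 0.00268).

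**Figure D1:**
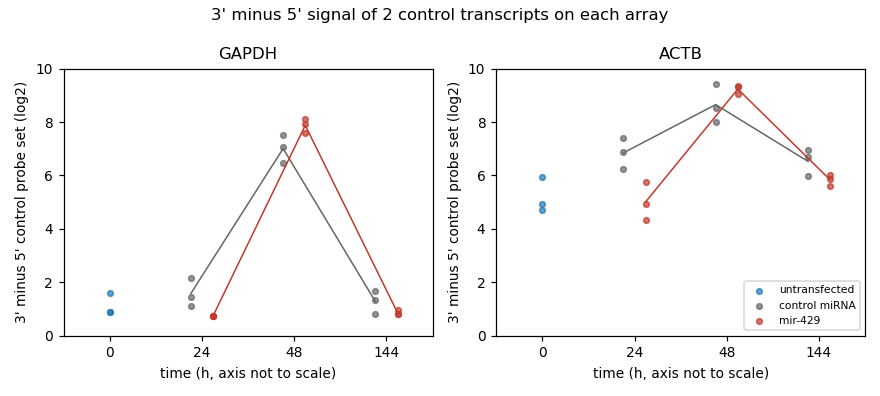
Difference between the 3' and 5' control probe sets (log2, vertical axis) of GAPDH and ACTB on each of the 21 arrays by time in h, with points for arrays and lines through the group means of each transfected arm; untransfected cells are points without a line. The 48 h arrays stood apart, with GAPDH means of 7.01 in control and 7.88 in mir-429 arrays.

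The comparison at 24 h asked which mRNAs differed a day after mir-429 transfection. Epithelial genes that could be tested rose, with 15 of 31 tested members higher and 0 lower. The list held 62 genes, 55 of them with a probe set, and those not among the 31 were too dim or had none. A gene could pass the filter through the arrays of a single group, so the share of the 31 may overstate the rise of the whole list. CDS1, a phospholipid synthesis enzyme that lay below the array median in 2 of 3 control arrays, rose by at least 2.44 (log2). The microtubule-binding MAP7 rose by 2.16 ± 0.23 (SE) and the desmosomal PKP2 by 1.78 ± 0.21. Described miR-200 family targets fell, with 16 of 45 lower and 7 higher (camera adjusted p = 0.0102; adjusted p = 0.508 with an estimated correlation). WIPF1, a partner of the actin regulator WASP, changed by -2.13 ± 0.13, the matrix protein fibronectin (FN1) by -1.70 ± 0.12 and the phosphatase PPM1F by -1.72 ± 0.14. ZEB1, a repressor of epithelial genes, changed by -1.29 ± 0.15 (limma adjusted p = 6.5e-06), while the related ZEB2 was at -0.43 ± 0.18 (adjusted p = 0.0893). Among the largest rises were ZBED2 at 2.23 or more and ZNF165 at 3.11 ± 0.37. The largest falls included HMOX1, the heme-degrading oxygenase, at -2.58 ± 0.23, BCL2A1 at -2.30 ± 0.19, the channel protein PANX1 at -2.21 ± 0.08 and the collagen cross-linking enzyme LOX at -2.09 ± 0.13.

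In all, 3425 of 12879 genes passed the threshold at 24 h, 1937 higher and 1488 lower, and 265 and 120 of them changed at least 2-fold. The epithelial call (camera adjusted p = 0.000251) held with an estimated correlation (adjusted p = 0.0488). That of the miR-200 targets was lost, as given above. YAP and TGF-beta response genes were also called higher (14 of 38 higher, 3 lower, adjusted p = 0.00684; adjusted p = 0.508 with an estimated correlation), including the matrix protein THBS1 at 1.06 ± 0.12 and PMEPA1 at 1.01 ± 0.11. Adjusted over the list alone, 15 epithelial genes were higher, 17 miR-200 targets were lower and 8 higher, and 16 YAP and TGF-beta genes were higher and 3 lower. Mesenchymal genes went both ways, 12 higher and 13 lower of 47, and the list was not called (adjusted p = 0.744). Among inflammatory genes, the cytokines IL1B and CSF3 changed by -1.59 ± 0.13 and -1.22 ± 0.12 and the neutrophil chemokine CXCL8 by -1.14 ± 0.15, but the list was not called (6 higher and 7 lower of 37; adjusted p = 0.744). For these lists the median and the mean differed in sign (0.09 and -0.06 for mesenchymal, 0.09 and -0.05 for inflammatory genes). In the 9 comparisons the median, mean and camera test differed in sign only for lists that camera did not call. Mitosis (17 higher, 7 lower of 71), interferon (4 higher, 3 lower of 44), hypoxia (9 higher, 6 lower of 42) and p53 target genes (11 higher, 5 lower of 31) were not called either, though fry put mitosis and p53 genes higher (adjusted p = 0.0123 and 0.0232). The mesenchymal marker VIM was at -0.11 ± 0.11. N-cadherin (CDH2) was at 0.27 ± 0.09 (adjusted p = 0.0333), a call lost without control 24 h replicate 3 (adjusted p = 0.156), without mir-429 24 h replicate 1 (adjusted p = 0.169), with the 3' to 5' covariate (0.17 ± 0.13) and after cyclic loess or quantile scaling. The epithelial markers CDH1 and EPCAM were too dim to be tested.

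With the 3' to 5' difference as a covariate, chosen after seeing the data, the count at 24 h was 614, of which 604 were also in the main count. The median size of the 3425 changes went from 0.58 to 0.45 and their median SE from 0.14 to 0.20. The median of the YAP and TGF-beta genes went from 0.24 to 0.13. The epithelial and miR-200 target lists were still called (both adjusted p = 2.29e-05). Without control 24 h replicate 3 the count was 2148 and without mir-429 24 h replicate 1 it was 2249.

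At 48 h the epithelial rise and the fall of miR-200 targets were again present. The fall of the targets had an adjusted p = 0.0629 with an estimated correlation. ESRP1, an epithelial splicing factor, rose by 2.92 ± 0.13, the protease inhibitor SPINT2 by 3.20 ± 0.22, MAP7 by 3.12 ± 0.23 and PATJ, a tight junction scaffold, by at least 1.90. ZEB1 changed by -1.72 ± 0.15 and ZEB2 by -1.12 ± 0.18 (adjusted p = 0.000215), and FN1 by -2.66 ± 0.12, LOX by -2.73 ± 0.13 and the actin-severing CFL2 by -1.03 ± 0.16. CXCL8 was at -3.13 ± 0.15, CXCL3 at -2.80 ± 0.16, CXCL1 at -2.37 ± 0.12 and CXCL2 at -2.12 ± 0.16. In control cells at 48 h these 4 were at 2.03, 1.65, 1.96 and 1.06 against untransfected cells. The inflammatory list was not called by camera (6 higher, 9 lower; adjusted p = 0.0816), while fry put it lower (adjusted p = 5.71e-05). CD274, which encodes the immune checkpoint ligand PD-L1, rose by 2.28 ± 0.20.

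The 48 h comparison called 2649 genes, 1200 higher and 1449 lower, and 1380 higher and 1181 lower without control 48 h replicate 3. Epithelial genes had 13 members higher and 1 lower (camera adjusted p = 8.14e-09; adjusted p = 0.00239 with an estimated correlation). Of the miR-200 targets, 19 were lower and 2 higher (adjusted p = 3.54e-06; adjusted p = 0.0629 with an estimated correlation). Mesenchymal genes had 16 lower and 8 higher (adjusted p = 0.0425; adjusted p = 0.468 with an estimated correlation), a call lost with the 3' to 5' covariate (median -0.16 before and -0.18 after, adjusted p = 0.0916) and without control 48 h replicate 2 (adjusted p = 0.0889) or mir-429 48 h replicate 2 (adjusted p = 0.11). DNA replication genes had 9 higher and 2 lower of 59 (adjusted p = 0.00485; adjusted p = 0.356 with an estimated correlation), with the cell cycle regulator E2F8 at 0.87 ± 0.12. Adjusted over the list alone, 16 epithelial genes were higher and 1 lower, 21 miR-200 targets lower and 3 higher, 17 mesenchymal genes lower and 9 higher, and 9 DNA replication genes higher and 2 lower. SEC23A, a coat protein of secretory vesicles, was at -1.23 ± 0.18 and its partner SEC24A at 1.29 ± 0.12. The glycolysis gene HK2 was at 0.71 ± 0.14, but its probe sets disagreed and their mean was at -0.28. All 48 h arrays had the low 5' signal given above, and fitting only these 6 arrays gave 916 genes.

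**Figure D2:**
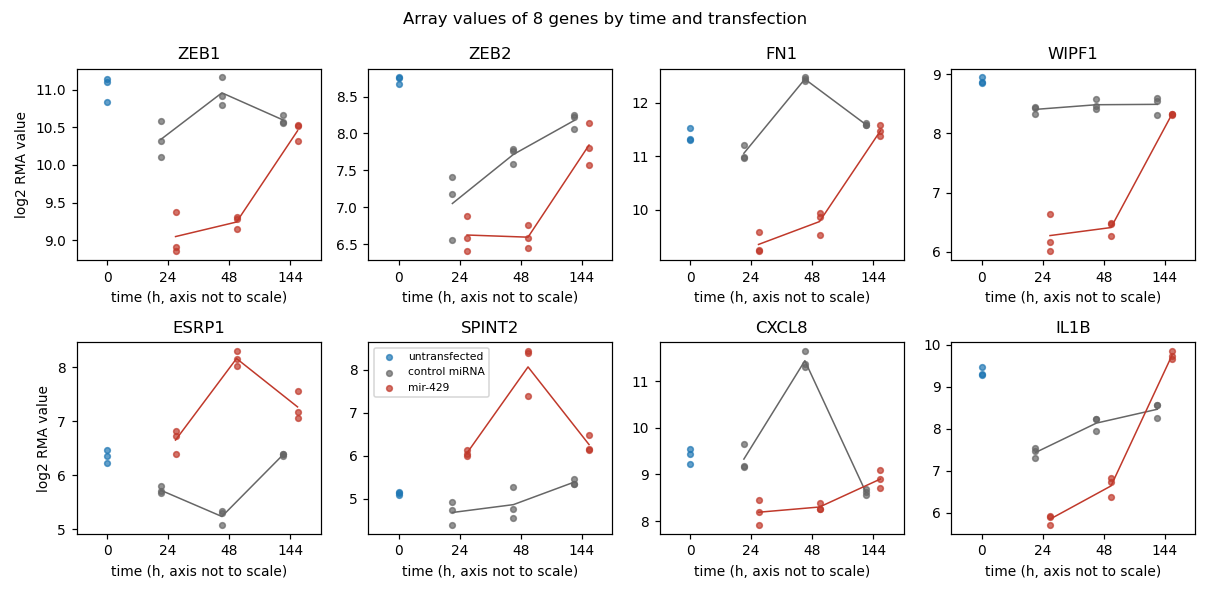
Log2 RMA values (vertical axis) of 8 genes on each array by time in h, with points for arrays and lines through the group means of each transfected arm; untransfected cells are points without a line. ZEB1 and FN1 were lower with mir-429 at 24 and 48 h and near control at 144 h, where the differences were -0.14 and -0.12.

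At 144 h epithelial genes were still higher, with 7 of 31 past the threshold and 0 lower, among them CDS1 at 1.75 or more, ESRP1 at 0.89 ± 0.13 and the desmosomal DSP at 0.86 ± 0.12. ZEB1 was at -0.14 ± 0.15 (adjusted p = 0.655), ZEB2 at -0.33 ± 0.18 and FN1 at -0.12 ± 0.12, and of the miR-200 targets 1 was called, the metalloprotease ADAM12 at -0.78 ± 0.12. Among the largest rises were GPR65, a proton-sensing receptor, at 4.08 or more, FGFBP1, a carrier of fibroblast growth factors, at 2.79 ± 0.17, ZBED2 at 1.01 or more and the collagenase MMP1 at 2.08 ± 0.17. IL1B, which was lower at 24 h, was higher at 144 h by 1.28 ± 0.13. The collagen gene COL5A1 was at -1.11 ± 0.17, and THBS1, which was higher at 24 h, was at -1.35 ± 0.12. THBS1 rose by about as much in these control arrays against untransfected cells, as given below. Its value thus does not show a fall below untransfected cells.

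The 144 h count was 754, with 191 higher and 563 lower, and the epithelial call had a camera adjusted p = 1.61e-08 (adjusted p = 0.00167 with an estimated correlation). Unfolded protein and amino acid stress genes were higher (6 of 46, 0 lower; adjusted p = 4.19e-09, and adjusted p = 0.00114 with an estimated correlation), including the stress transcription factor DDIT3 at 0.74 ± 0.15. Cholesterol synthesis genes were higher (3 of 23, 0 lower; adjusted p = 5.7e-07, and adjusted p = 0.00929 with an estimated correlation). DNA replication genes were lower (10 of 59, 0 higher; adjusted p = 7.3e-07, and adjusted p = 0.0306 with an estimated correlation), with the transcription factor E2F2 at -1.14 ± 0.15 and the replication factor MCM10 at -0.73 ± 0.10. Inflammatory (5 higher), p53 (3 higher, 1 lower), hypoxia (3 higher) and actin lists (1 of 55 higher) were called higher with the preset correlation (adjusted p = 0.00201, 0.00591, 0.00702 and 0.0115) and not otherwise by camera (adjusted p = 0.127, 0.0691, 0.127 and 0.156 with an estimated correlation). Fry called the first 2 and not the others (adjusted p = 0.0407, 0.0349, 0.0751 and 0.16). Adjusted over the list alone, 15 epithelial genes were higher and 1 lower, 9 stress and 4 cholesterol synthesis genes higher, and 15 DNA replication genes lower.

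The actin call at 144 h was also lost with the 3' to 5' covariate (median 0.035 before and 0.034 after, adjusted p = 0.107), after cyclic loess (adjusted p = 0.103) and without mir-429 144 h replicate 1 (adjusted p = 0.0645). The share of higher genes at 144 h was 25.3%, and 43.8% after cyclic loess and 37.0% after quantile scaling. As deposited, mir-429 144 h replicate 1 had the lowest median of all arrays, 3.95, against 4.22 and 4.21 in replicates 2 and 3. The excess of lower genes may thus depend in part on scaling and on that array. The count was 496, 326 and 404 without control 144 h replicates 1, 2 and 3, and 410 and 400 without mir-429 144 h replicates 1 and 2. Without the 48 h arrays in the fit, a setting chosen after seeing the data, it was 1160. With only the arrays compared in the fit, it was 1017.

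**Figure D3:**
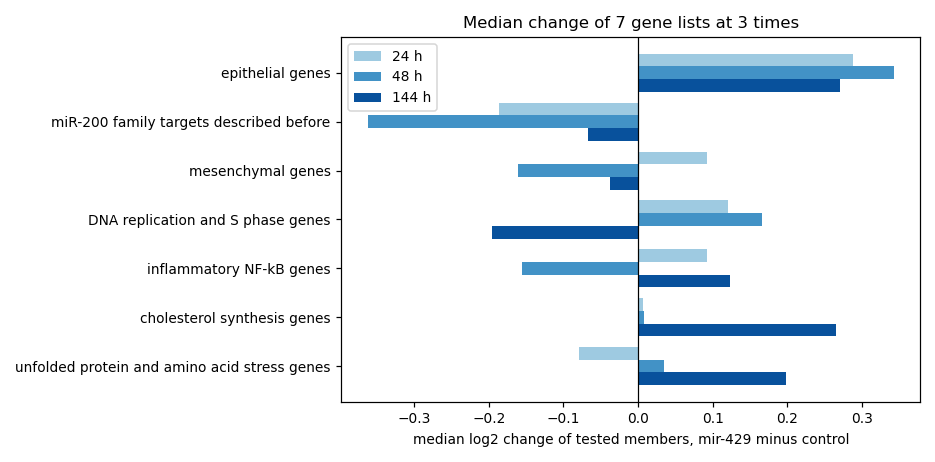
Median log2 change (horizontal axis) of the tested members of 7 gene lists, mir-429 minus control, with 1 bar for each of 3 times. The epithelial median stayed above 0 at 0.29, 0.34 and 0.27, and that of the miR-200 targets was -0.19, -0.36 and -0.07.

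Averaged over the 3 times, FGFBP1 rose by 2.11 ± 0.10 (n = 9 arrays per arm). CDS1, ZBED2, GPR65 and the collagen gene COL8A1, dim in control arrays, rose by at least 2.34, 2.26, 1.94 and 1.18. The largest falls were OSTM1 at -1.84 ± 0.09, HMOX1 at -1.83 ± 0.14, LOX at -1.73 ± 0.08, DNER at -1.62 ± 0.09 and CD93, dim in mir-429 arrays, at -1.05 or lower. This comparison called 3602 genes, 1621 higher and 1981 lower, and 1897 higher and 1735 lower after cyclic loess. Epithelial genes had 17 members higher and 0 lower (camera adjusted p = 1.1e-09; adjusted p = 0.00151 with an estimated correlation), and miR-200 targets 19 lower and 6 higher (adjusted p = 0.000412; adjusted p = 0.145 with an estimated correlation). Called higher with the preset correlation but not an estimated one were p53 targets (11 higher, 5 lower; adjusted p = 0.0305, and adjusted p = 0.163 with an estimated correlation) and unfolded protein genes (13 higher, 3 lower; adjusted p = 0.0268, and adjusted p = 0.145 with an estimated correlation). Fry called both (adjusted p = 0.000259 and 0.000191). The p53 call was lost without control 24 h replicate 3 (adjusted p = 0.055) or mir-429 144 h replicate 1 (adjusted p = 0.0562), and both calls after cyclic loess (adjusted p = 0.0846 for both). Adjusted over the list alone, 18 epithelial genes were higher and 1 lower, and 22 miR-200 targets were lower and 6 higher.

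Genes called at 24 h were followed on the arrays of later times, which had no part in their averages. The 1937 higher genes had a median of 0.60 at 24 h, 0.23 at 48 h and -0.04 at 144 h, and 78.8% and then 43.2% kept their sign. The 1488 lower genes had medians of -0.56, -0.26 and -0.06, with 81.5% and 59.9% keeping their sign. The median of all genes at 144 h was -0.04. Between 24 and 48 h, 628 higher and 594 lower genes were shared, against 180.5 and 167.4 for independent lists. Between 24 and 144 h, 59 higher and 105 lower genes were shared, against 28.73 and 65.05. Of the genes higher at 24 h, 72 were called lower at 144 h, and 21 of the lower genes were called higher. Neither number was above what independent lists of these sizes would share, so they do not show a reversal of the 24 h effect. Across all genes the effects at 24 and 48 h correlated at r = 0.519 and those at 24 and 144 h at r = 0.0691. At all 3 times 48 genes were higher, among them ESRP1, SPINT2, MAP7, DSP and PATJ, and 76 were lower, among them CD93, OSTM1 and the matrix protein TGFBI.

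The change of the effect between 24 and 48 h was tested directly. ESRP1 (1.99 ± 0.19), TMEM200A (2.04 ± 0.20) and SPINT2 (1.82 ± 0.32) had a higher effect at 48 h, and CXCL3 (-2.02 ± 0.23) and the epithelial cytoskeletal linker EPPK1 (-2.28 ± 0.31) a lower one. In all 630 genes differed, 225 upward and 405 downward, and 489 upward and 437 downward without control 48 h replicate 3. Epithelial genes moved upward (4 upward, 1 downward; adjusted p = 0.0212), and mesenchymal (6 downward; adjusted p = 0.034) and YAP and TGF-beta genes (6 downward; adjusted p = 0.0038) moved downward. None of these calls held with an estimated correlation (adjusted p = 0.416, 0.426 and 0.426 with an estimated correlation), and the mesenchymal and YAP calls were lost with the 3' to 5' covariate too (adjusted p = 0.153 for both). Their medians were -0.10 and -0.18 before and -0.11 and -0.22 after, while the median SE of the members rose from 0.21 to 0.31 and from 0.19 to 0.27. The epithelial call was lost without control 24 h replicate 2 (adjusted p = 0.073). The mesenchymal call was lost without control 24 h replicate 1, control 48 h replicate 1, mir-429 24 h replicate 2 or mir-429 48 h replicate 2 (adjusted p = 0.0646, 0.0581, 0.0536 and 0.14). With that covariate the count was 2, ESRP1 and TMEM200A, so that the calls of SPINT2, CXCL3 and EPPK1 were lost, at 1.38 ± 0.49, -2.07 ± 0.37 and -1.83 ± 0.47. The median size of the 630 changes went from 0.83 to 0.62 and their median SE from 0.19 to 0.29. The count was 419, 1973 and 166 without control 24 h replicates 1, 2 and 3, and 1074 and 374 without control 48 h replicates 1 and 2. It was 165, 389 and 405 without mir-429 24 h replicates 1, 2 and 3, 307 without mir-429 48 h replicate 3, and 58 when only the arrays compared were fitted.

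From 48 to 144 h the effect on miR-200 targets moved upward (11 of 45 upward, 3 downward; adjusted p = 4.31e-06, and adjusted p = 0.0436 with an estimated correlation), and that on epithelial genes downward (10 downward, 1 upward; adjusted p = 0.00138, and adjusted p = 0.0436 with an estimated correlation). MMP1 moved by 4.24 ± 0.25, CXCL8 by 3.42 ± 0.22 and IL1B by 2.78 ± 0.18, and the inflammatory list with them (9 upward, 3 downward; adjusted p = 9.72e-06, and adjusted p = 0.0436 with an estimated correlation). DNA replication genes moved downward (15 of 59; adjusted p = 1.66e-08, and adjusted p = 0.0429 with an estimated correlation) and cholesterol synthesis genes upward (3 of 23; adjusted p = 0.000416, and adjusted p = 0.0436 with an estimated correlation). With the 3' to 5' covariate the median of the miR-200 targets went from 0.35 to 0.22 and that of the cholesterol synthesis genes from 0.28 to 0.12, and both stayed called (adjusted p = 0.002 and 0.0269). ZNF165 moved by -3.82 ± 0.52 and CST6, a protease inhibitor, by -2.80 ± 0.29. Both were dim in some groups, and with those groups raised to the array median they moved by -2.66 and -2.14.

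In all 1219 genes differed between the effects at 48 and 144 h, 495 upward and 724 downward, and 792 with the 3' to 5' covariate. The upward share was 40.6%, and 51.5% after cyclic loess. Unfolded protein (5 upward, 1 downward), interferon (2 upward), actin (6 upward, 2 downward) and mesenchymal genes (8 upward, 6 downward) were called upward (adjusted p = 0.0113, 0.0402, 0.0312 and 0.0312), and none with an estimated correlation (adjusted p = 0.0659, 0.253, 0.253 and 0.264 with an estimated correlation). These calls were lost with the covariate as well (adjusted p = 0.0634, 0.239, 0.38 and 0.134). Fry did not call the interferon and actin lists (adjusted p = 0.107 and 0.0516). The 4 medians were 0.17, 0.14, 0.068 and 0.035 before and 0.080, 0.095, 0.017 and 0.14 after. The interferon, actin and mesenchymal calls were lost without control 48 h replicate 2 (adjusted p = 0.0724, 0.157 and 0.0839) and without mir-429 144 h replicate 1 (adjusted p = 0.0821, 0.0825 and 0.0656). The actin and mesenchymal calls were lost without mir-429 48 h replicate 2 (adjusted p = 0.0929 and 0.0879), and the interferon call without control 48 h replicate 3, control 144 h replicate 3 or mir-429 48 h replicate 3 (adjusted p = 0.153, 0.0755 and 0.0691).

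Control transfection was compared with untransfected cells to show what changed without mir-429. At 24 h HMOX1 rose by 3.70 ± 0.23, the matrix protease MMP3 by at least 2.90 and AKR1C1, a ketosteroid reductase, by 3.29 ± 0.11. AKR1C1 has close paralogs that its probe set may not separate. Mitosis genes fell (39 of 71 lower, 2 higher; camera adjusted p = 1.11e-08, and adjusted p = 0.0336 with an estimated correlation), with the kinesin KIF14 at -1.44 ± 0.13 and the spindle protein ASPM at -0.97 ± 0.10. Cholesterol synthesis genes fell (12 of 23 lower, 0 higher; adjusted p = 6.97e-05; adjusted p = 0.055 with an estimated correlation), as did miR-200 targets (23 of 45 lower, 1 higher; adjusted p = 3.48e-05; adjusted p = 0.0727 with an estimated correlation), with ZEB2 at -1.68 ± 0.18. Actin genes were called lower (19 of 55, 0 higher; adjusted p = 0.023; adjusted p = 0.273 with an estimated correlation) and unfolded protein genes higher (19 higher, 5 lower of 46; adjusted p = 0.0148; adjusted p = 0.0922 with an estimated correlation). Adjusted over the list alone, 40 mitosis genes, 12 cholesterol synthesis genes and 24 miR-200 targets were lower. In all 4897 genes were called, 2352 higher and 2545 lower. More were higher than lower after quantile scaling (2651 and 2405), with the mean of probe sets (1887 and 1800), with array weights (4260 and 3997) and without untransfected replicate 1 (2288 and 2266). The count was 2118 with the 3' to 5' covariate. The median size of the 4897 changes went from 0.59 to 0.51 and their median SE from 0.14 to 0.18. The covariate ended the actin call (median -0.10 before and -0.12 after, adjusted p = 0.0846). The 3 control comparisons share the untransfected arrays, and mir-429 against control at a given time shares its control arrays with the control comparison of that time, so chance values are shared between them.

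At 48 h control cells had the transcription factor MYC at 3.04 ± 0.21, the matrix protein SPP1 at 2.89 ± 0.15, CXCL1 at 1.96 ± 0.12 and NFKBIA, an inhibitor of NF-kB, at 1.91 ± 0.14. The cholesterol synthesis enzymes FDPS and MVK were at -1.18 ± 0.10 and -1.19 ± 0.12, and 17 of 23 genes of that list were lower and 1 higher (adjusted p = 0.00327; adjusted p = 0.347 with an estimated correlation). Inflammatory (15 higher, 7 lower of 37; adjusted p = 0.00692) and YAP and TGF-beta genes (20 higher, 7 lower of 38; adjusted p = 0.000136) were called higher, and neither with an estimated correlation (adjusted p = 0.347 for both with an estimated correlation). Adjusted over the list alone, 17 cholesterol synthesis genes were lower, and 15 inflammatory and 22 YAP and TGF-beta genes were higher. The count was 7022, with 2376 higher and 4646 lower, and the median of all genes was -0.16 (-0.06 after cyclic loess). These arrays had the low 5' signal, and of 2280 genes whose 2 brightest probe sets both passed, 26.8% had them in opposite directions. For control at 24 h, without 48 h arrays, this was 17.5% of 1044 genes. With the 3' to 5' covariate the count was 76, with 45 higher and 31 lower. The median of the 7022 changes, taken in their first direction, went from 0.71 to 0.69 and their median SE from 0.15 to 0.57, and 32.0% went below 0.5 of their size or reversed. MYC and SPP1 were still called. CXCL1, NFKBIA, FDPS and MVK were not, at 2.02 ± 0.50, 1.81 ± 0.55, -1.09 ± 0.39 and -1.10 ± 0.51. The cholesterol synthesis median went from -0.82 to -0.45 (adjusted p = 0.33), and the inflammatory median from 0.13 to 0.44 with the call kept.

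At 144 h 61 genes differed between control and untransfected cells, 36 higher and 25 lower. THBS1 was at 1.39 ± 0.12, EFEMP1, an extracellular matrix protein, at 1.22 ± 0.11, TMEM158 at -1.74 ± 0.17 and the surface protein CDCP1 at -1.34 ± 0.16. DNA replication genes were called higher as a list (median 0.14, with 4 of 59 members higher adjusted over the list alone; adjusted p = 7.61e-05; adjusted p = 0.259 with an estimated correlation). The count was 25 without untransfected replicate 2 or 3, and 32, 28 and 25 without control 144 h replicates 1, 2 and 3. It was 18 with the 3' to 5' covariate, where the median size of the 61 changes went from 0.75 to 0.70 and their median SE from 0.13 to 0.14. Fitting only the 6 arrays gave 664, with 240 higher and 424 lower.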

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

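Of the tests in this part, the splits of the arrays without removal of a shared effect and the comparison of 24 h calls with the control change at 48 h were set out beforehand; the others were chosen after the results were seen.

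The mir-429 effect differed between 24 and 48 h for 630 genes and between 48 and 144 h for 1219 genes, by tests of the difference itself. From 24 to 48 h ESRP1 changed by 1.99, TMEM200A by 2.04, SPINT2 by 1.82, LRRN4 by 1.57, EPPK1 by -2.28, MOBP by -2.04, CXCL3 by -2.02 and RFFL by -2.00, where RFFL was at -0.58 ± 0.61 with the 3' to 5' covariate. List medians differed by 0.22 for epithelial, -0.10 for mesenchymal and -0.18 for YAP and TGF-beta genes. From 48 to 144 h MMP1 changed by 4.24, CXCL8 by 3.42, GPR65 by 2.99, IL1B by 2.78, ZNF165 by -3.82, CST6 by -2.80, ZBED2 by -2.58 and SPOPL by -2.56. MOBP, RFFL, GPR65, ZNF165, CST6 and ZBED2 were dim in some groups, and with those raised to the array median they changed by -1.08, -1.65, 2.73, -2.66, -2.14 and -2.55. List medians differed by 0.35 for miR-200 targets, -0.22 for epithelial, 0.035 for mesenchymal, 0.068 for actin, -0.28 for DNA replication, 0.14 for interferon, 0.32 for inflammatory, 0.28 for cholesterol and 0.17 for unfolded protein genes. In data outside the gene comparisons, the GAPDH control probe sets gave a 3' minus 5' signal of 7.01 in control and 7.88 in mir-429 arrays at 48 h.

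The control arrays at 48 h differed from untransfected cells in 7022 genes. RNA degradation predicts that probe sets of a gene move apart, and 26.8% of genes with both probe sets called moved in opposite directions, against 7.07% for mir-429 against control at 48 h. Control at 24 h against untransfected cells, without 48 h arrays, gave 17.5%, so a large share was not peculiar to the 48 h arrays. That comparison had a gap in the 3' to 5' difference of its own, with means of 4.21 in control and 3.15 in untransfected arrays. Its share therefore does not count against degradation, which stays open as a possible explanation. For the 1668 genes whose probe sets moved the same way, culture time after transfection and RNA quality cannot be told apart, because every 48 h array had the low 5' signal.

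The mir-429 arrays at 24 h had a smaller 3' to 5' difference than the controls, so RNA integrity could account for calls there. Of 1262 genes called at both 24 and 48 h, 3.17% moved in opposite directions although the integrity difference had the opposite sign at 48 h (exact permutation p = 0.2), which argues against integrity as the whole cause for these genes; their effect still correlated with slopes on the 3' to 5' signal, taken from arrays of other times, at r = -0.265. For the 2163 genes called at 24 h and not at 48 h, the test set out beforehand gave a median difference of 0.0638, outside what integrity predicted. That bound was a poor one, since the same slopes correlated with their 24 h effect at r = -0.569 across these genes and at -0.276 across all tested genes, in the direction integrity predicts. With the covariate their median size went from 0.54 to 0.39 and their median SE from 0.14 to 0.20, so that 115 stayed past the threshold and 99.6% kept their sign; part of these calls may thus reflect RNA quality, and how much stays open.

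CXCL8, CXCL1, CXCL2 and CXCL3 were lower with mir-429 at 48 h, and MMP1 and IL1B were higher at 144 h. Of the inflammatory list and MMP1, 10 genes moved upward between these times, by a median of 2.07. Their median in mir-429 cells at 144 h against untransfected cells was -0.0204, with a bootstrap interval from -0.51 to 0.89. That of control cells at 144 h was -0.287, with members from -0.89 to 0.77. Against control, the median with mir-429 was -1.89 at 48 h and 0.20 at 144 h. In control cells at 48 h their median against untransfected cells was 1.61, with members from -1.22 to 2.03. The control median was thus lower at 144 h than at 48 h. For the 10, a fall of the controls between these times may therefore make up much of the move, and these values do not exclude it. Whether a fall of the controls below untransfected cells accounts for the difference at 144 h also stays open. MMP1, IL1A and IL1B, the 3 called higher at 144 h, stood above untransfected cells by 1.41, 1.09 and 0.396 in mir-429 arrays and at -0.67, -0.024 and -0.89 in controls, which argues against such a fall as the whole cause for them. The median change of the 10 between 48 and 144 h was 2.07, and 2.25 with the 3' to 5' covariate. The interval over genes then ran from 1.01 to 3.19, and 9 of 10 were still past the threshold. This does not decide on degraded RNA, because the 10 were chosen by the same change on the same arrays. The covariate also rests on differences between arrays within groups, while all 48 h arrays had the low 5' signal. The inflammatory list was tested as mRNA levels only, and inflammatory signalling itself was not measured.

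Other splits of the arrays were compared with the real groups. Each comparison of 3 against 3 arrays has 10 splits, too few for a share under 0.05. The real counts were 3425, 2649 and 754 for mir-429 at 24, 48 and 144 h and 4897, 7022 and 61 for the controls, and the highest other split gave 96 for mir-429 at 48 h and 0 elsewhere (limma, adjusted p). For the averaged effect 1 of 100 splits, the real one, reached 3602 (highest other 748), which argues against chance there. A difference in culture or batch between the arms would give the same result, and the labels do not say whether there was one. For 144 against 48 h 1 of 100 reached 1219 (highest other 1123), and for 48 against 24 h 16 of 100 gave 630 genes or more, up to 4102. The splits with as many genes left the labels of 1 time whole or exchanged them fully, which turns an effect shared by both times into a difference, a structure of the samples, so these splits are no reference without change. After the shared effect was removed, 2 of 200 splits reached 630, the real one and one with 743. For 144 against 48 h 1 of 200 reached 1219 (highest other 93). The shared effect was estimated from the real groups, so the removal may favour the real split. For 144 against 48 h, where the splits set out beforehand also gave 1 of 100, the values argue against chance. For 48 against 24 h they do not decide, since another split gave more genes and those set out beforehand gave 16 of 100.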

How the results depend on the processing

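Of the settings in this part, the 3' to 5' covariate, the fit without the 48 h arrays and the lists with 1 array left out were chosen after the data were seen. Across settings, 5190 values of named genes kept their direction and their side of the threshold, 336 lost the call, 4 gained it and 3 reversed; for the lists the numbers were 2061, 73, 56 and 0, and 5 gene and 89 list values that were called in neither setting changed sign. Unless said otherwise the cause was not tested. Fry, a test of a different question, also passed lists that camera did not call and that are not named with the comparisons. These were DNA replication genes (higher) for mir-429 at 24 h, and interferon (lower), p53 and unfolded protein genes (higher) at 48 h. In the averaged effect they were mesenchymal and inflammatory (lower) and cholesterol synthesis genes (higher), and inflammatory genes (downward) between 24 and 48 h. For control they were epithelial and mesenchymal genes at 24 h and miR-200 target, epithelial, actin, DNA replication and hypoxia genes at 48 h, all lower. Counts moved by over 1.5 times as follows. Without a filter on dim probe sets 263 genes differed between 24 and 48 h and 39 between control at 144 h and untransfected cells, and with the filter at the 75th percentile 947 and 114, where the number of genes tested differs by construction. The same 2 counts were 316 and 35 with the mean of all probe sets of a gene, and 951 and 105 with trend and robust options. That mean put HK2 at -0.027 at 24 h and -0.28 at 48 h. Array weights, whose fit stopped before its convergence tolerance, gave 6205, 1681 and 2437 genes for mir-429 at 24, 48 and 144 h, 1110 between 24 and 48 h, and 8257 and 4006 for control at 24 and 144 h. The covariate gave 614 genes for mir-429 at 24 h, 2 between 24 and 48 h, 792 between 48 and 144 h, and 2118, 76 and 18 for control at 24, 48 and 144 h; PSMC3 in control at 48 h was then at 0.035. Fitting only the arrays compared gave 916 for mir-429 at 48 h, 58 between 24 and 48 h and 664 for control at 144 h. Leaving out the 48 h arrays gave 1160 for mir-429 at 144 h. At a change of at least 2-fold, a smaller set by construction, the counts were 385, 429 and 119 for mir-429 at 24, 48 and 144 h, 106 averaged, 184 between 24 and 48 h, 401 between 48 and 144 h, and 605, 1859 and 16 for control.

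The medians at later times of genes called at 24 h moved too. At 48 h those of higher and lower genes were 0.26 and -0.31 without a filter, and that of higher genes 0.28 with the mean of probe sets. With the covariate, which called fewer genes at 24 h, they were 0.71 and -0.69 at 48 h and 0.020, a reversed sign, and -0.17 at 144 h. For genes changed at least 2-fold at 24 h they were 0.82 and -0.97 at 48 h, and -0.18 for lower genes at 144 h.

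Leaving out 1 array at a time, counts ran from 2148 to 4033, 2106 to 2611 and 326 to 659 for mir-429 at 24, 48 and 144 h, 3113 to 4027 averaged, 165 to 1973 between 24 and 48 h, 819 to 1484 between 48 and 144 h, and 3483 to 5257, 6075 to 6873 and 25 to 62 for control. The medians of genes called at 24 h ran from 0.15 to 0.34 and -0.41 to -0.20 at 48 h, and from -0.054 to -0.010 and -0.092 to -0.025 at 144 h. The list calls lost in this way are given with each comparison.

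The replicate block gave 3367, 2572 and 717 genes for mir-429, 3534 averaged, 638 and 1162 for the differences between times, and 4859, 6966 and 60 for control. Replicate numbers were not taken as pairs: deviations of same-numbered arrays correlated at 0.279, 0.0906 and 0.184 at 24 h, where 3 of 3 arrays correlated best with their own number, and below 0 for some pairs of other times. The test of mir-429 seed matches was not run. The 6896 genes set aside did not lie above the array median in at least 3 arrays, and nothing is said about their changes.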

Other observations

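Both tests in this part were chosen after the genes concerned had been seen, and 18 tests (2 lists in 9 comparisons) were run.

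Genes of the oxidative stress response controlled by NRF2 were higher in control cells at 24 h than in untransfected cells. Of 24 tested, 22 were higher and 0 lower, with a median of 0.90 (camera with an estimated correlation, p = 5.48e-05, and 0.000986 adjusted over the 18 tests). The median was 0.89 after cyclic loess, 0.93 after quantile scaling and 0.94 with the 3' to 5' covariate. The list was written after HMOX1 and AKR1C1 had been seen, so this is no independent evidence. HMOX1 itself was lower with mir-429 at 24 h, at -2.58, which raised the hypothesis that mir-429 cells might have had a weaker stress response. Against control at 24 h the list had a median of -0.01705, with a 95% interval from -0.114 to 0.223 and 3 members higher and 3 lower. HMOX1 had lost 69.6% of its control rise, and the same share would need a median of -0.617 in the other 23 genes. Theirs was -0.0144, with a 95% interval from -0.108 to 0.223, which argues against a response weakened that much. Both intervals take the genes as independent and leave out the spread between cultures. HMOX1 was chosen for its large changes, which share the control arrays, so its share may be too high. At 48 h the list was at -0.098 against control, with 0 members higher and 7 lower, and from 48 to 144 h it moved by 0.19. Both passed with the preset correlation (adjusted p = 0.0128 for both) and neither with an estimated one (adjusted p = 0.206 for both with an estimated correlation), so a smaller or later weakening stays open.

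Zinc finger genes named ZNF were lower with mir-429 at 144 h, where 32 of 329 were lower and 1 higher, with a median of -0.1914 against -0.04 for all genes. A shift of this family may therefore be present (camera with an estimated correlation, p = 0.0165), but adjusted over the 18 tests p was 0.149, so it did not pass a correction for the tests run. The direction was kept under each scaling, with medians of -0.11 after cyclic loess, -0.12 after quantile scaling and -0.21 with the 3' to 5' covariate.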
